A study of Mus musculus with 2 samples.

How the data were processed

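DNase-seq was measured in hippocampus of female B6CASTF1/J mice, in 2 libraries that the labels number as biological replicates 1 and 2. The labels give the tissue type as layer of hippocampus, which is called hippocampus here. Each was made from a pool of 2 biosamples. The labels place both libraries in 1 group, so no comparison between groups was made, and the labels do not say whether the pools came from different animals. Spreads between the libraries may therefore be partly technical.

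For each library the authors deposited 2 peak lists, a footprint list and a list of base intervals with a false discovery rate. Per the labels and the deposited notes, these were made from that library's own mm10 alignments and not from pooled libraries. The aligner, the peak caller, the footprint tool and their versions are not given in the sources used here. Reads of a cross between strains were placed on the reference assembly, and how this affects sites that differ between the strains was not tested. The deposited peak height is a signal that is never negative. Its values were whole multiples of 1 step per library in 100% of peaks, within 0.05 of a step, as a count times a constant would be. What the constant stands for is not given in the sources used here. That signal was used to describe, rank and match peaks, with no count test. The deposited false discovery rates (a p-value type unit) list only intervals below 0.05. Every peak of the larger list held a base below 0.05, and every peak of the smaller list a base below 0.001. The larger list was the main one, and the smaller list, with 55102 and 78377 peaks, the stricter alternative. The deposited footprints carry the p-value type threshold 0.01 in every row, so no footprint was ranked.

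Replicate 1 listed 29.3 Mb of bases below 0.05 and replicate 2 listed 40.6 Mb, of which 24.9 Mb were listed in both. If the signal is scaled to 1000000 cuts (1 M) per library, the libraries held 165 M and 126 M cuts, and the median peak 99 cuts in replicate 1 and 73 in replicate 2. Wilson 95% intervals cover counting error only.

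Overlaps were found with bedtools 2.31.1 with a minimum of 1 bp. Chance overlap was the mean of 20 placements of the peaks within their chromosomes on assembled bases, or of the footprints within their own peaks, and of 3 placements for reciprocal overlaps. Peaks were paired as mutual best overlaps for correlations. Genes were the protein-coding genes of GENCODE M21, and a promoter was 500 bp on either side of any annotated transcript start. A gene's promoter signal was that of the highest peak touching this window. Peaks were placed by midpoint in promoter, exon, intron or intergenic sequence, in that order, and compared with assembled bases of chromosomes 1 to 19, X and Y. Exons and introns were those of all annotated genes.

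A total of 24 gene lists and 21 motifs, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The lists covered hippocampal cell types, neighbouring brain regions, other tissues, Hox and olfactory receptor genes. List members were matched by symbol, and Nov and Ctgf were matched through their newer symbols Ccn3 and Ccn2. Each list was compared with all other protein-coding genes by a two-sided Fisher's exact test, adjusted over the 24 lists by the Benjamini-Hochberg method. Genes in a list are not independent replicates, and these p-values describe the lists within these libraries. The alternative with matched lists drew 10000 random lists with the same numbers in 10 bins of the observed to expected CpG ratio around the gene's 5' end. For motifs, matches of a consensus on either strand in merged peaks were compared with matches of the reversed consensus by a two-sided Fisher's exact test in each library. A motif was called when the adjusted p was below 0.05 in the same direction in both libraries. Matches are not independent replicates, and these p-values describe the matches within these libraries. The libraries share many peaks, so results in both are not independent of each other. The reversed consensus does not keep CpG content.

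The rule for named genes took, per list, the 2 members with the highest mean promoter signal among those with a peak in both libraries and the first 2 by alphabet with a peak in neither. It also took the 10 shared peaks with the highest mean signal and, for each library, the 5 highest peaks without an overlap in the other. The nearest protein-coding gene is given for each. Some genes that the rule takes are not reported here. All motifs were reported.

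Alternatives were a reciprocal overlap of 0.5, the stricter peaks, the 50000 highest peaks per library, a 2000 bp window, the gene record's 5' end alone, each library left out, CpG-matched lists, footprints inside peaks of both libraries, all bases of a match in a footprint, peaks outside promoters, and signal divided by the library median over shared peaks. A distance of 200 bp for shared peaks and the placement of motif matches within their own peaks were added after the data were seen. Placement used 10000 draws over all start positions in the same peak, so the smallest p it can give is 0.0002.

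The functions were tested on simulated data. All 7000 of 10000 intervals planted as shared were recovered. Of 100 simulated lists of 15 genes with a share of 0.2, against 0.7 elsewhere, 99 were called at an unadjusted 0.05. Of 100 unchanged lists, 2 were called. Smaller differences were not simulated. The matched-list test called 3 of 100 unchanged lists. Of planted motif sites covered at 80%, 79.8% were found covered. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.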

Results

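DNase-seq was used to map open chromatin in mouse hippocampus. In this assay the enzyme DNase I cuts nuclear DNA where it is accessible, and sites with many cuts are called as peaks. Short stretches with few cuts inside such sites, called footprints, can mark places where a bound protein shields the DNA. The tissue, labelled layer of hippocampus, came from female mice of strain B6CASTF1/J, an F1 cross, aged 8 to 10 months. There was 1 group with 2 libraries, and each library was made from a pool of 2 biosamples, so the series described a single tissue and had no treated or control arm. The question addressed was which promoters and distal sites were open in this tissue and how far the 2 libraries shared them. Replicate 1 had 98902 peaks covering 20.2 Mb and replicate 2 had 130199 peaks covering 26.5 Mb. The median peak width was 201 bp in replicate 1 and 200 bp in replicate 2. The deposited signal rose in fixed steps of 0.00606 in replicate 1 and 0.00795 in replicate 2. If the signal is scaled to 1000000 cuts (1 M) per library, the libraries held 165 M and 126 M cuts. The sources used here do not state the scale. The median peak stood at 99 steps in replicate 1 and 73 steps in replicate 2. All positions are 1-based on mm10.

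Open sites of the hippocampus were largely found again in the other library when they were strong, and less often when they were weak. Of the replicate 1 peaks, 81.6% overlapped a replicate 2 peak by at least 1 bp (Wilson 95% interval 81.4 to 81.8%, 80698 of 98902). Of the replicate 2 peaks, 62.0% overlapped a replicate 1 peak (61.8 to 62.3%, 80766 of 130199). Peaks shuffled within their chromosomes overlapped at 2.10% and 1.60%. In the quintile of peaks with the highest signal the shares were 99.3% for replicate 1 and 98.5% for replicate 2. In the quintile with the lowest signal they were 54.7% and 21.1%. Across 78993 pairs of matched peaks, log2 signal had a Pearson r of 0.928 and the signal a Spearman rho of 0.898. These correlations are across peaks, which are not independent replicates. The signal of matched peaks was higher in replicate 2 by a median of 0.22 on the log2 scale, and 98.2% of pairs lay within 2-fold of that median. With 2 libraries, the intervals cover counting error within the lists and not the spread between animals.

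**Figure D1:**
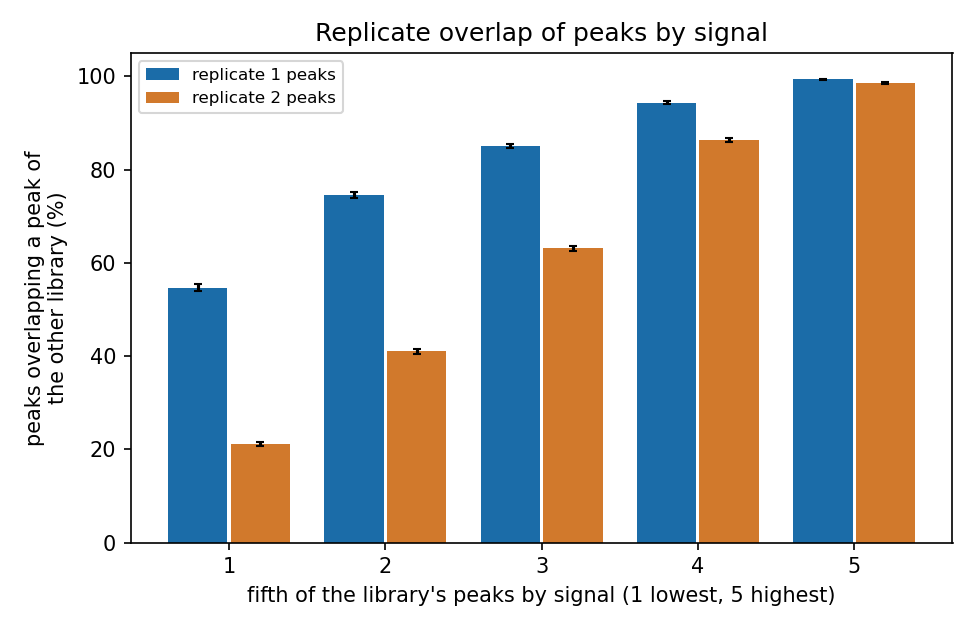
Bars show the share of each library's peaks (vertical axis, %) that overlapped a peak of the other library by at least 1 bp, for quintiles of the peaks ranked by signal (horizontal axis), with Wilson 95% intervals. The share ran from 54.7% to 99.3% for replicate 1 and from 21.1% to 98.5% for replicate 2.

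Promoters were the location most over-represented among open sites. Peaks with their midpoint within 500 bp of a protein-coding transcript start made up 18.7% ± 2.96 of peaks (mean ± SD, n = 2), against 2.02% of the assembled bases, a 9.24-fold excess. Exons held 6.59% ± 0.70 of peaks against 4.10% of bases. Introns held 39.6% ± 2.08 against 40.2% of bases, and intergenic sequence held 35.1% ± 1.58 against 53.6%. Promoter peaks were also the strongest, with a median signal of 1.08 in replicate 1 and 1.20 in replicate 2, against 0.497 and 0.493 for intergenic peaks. Among peaks without an overlap in the other library, 16.9% of those in replicate 1 and 8.24% of those in replicate 2 lay at promoters. Their median GC content was 53.5% in replicate 1 and 46.9% in replicate 2. With a promoter window of 2000 bp the promoter share was 28.4% ± 3.82 (n = 2), against 6.68% of the bases.

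The 10 strongest shared sites were 6 promoters, 3 exonic sites and 1 intergenic site. The highest mean signal, 29.2 ± 6.78 (SD, n = 2), was on chromosome 17 at 39846781 to 39846920, inside a gene annotated as ribosomal RNA. A site in an exon of Cers5, a ceramide synthase gene, on chromosome 15 at 99735661 to 99735940 reached 21.03 ± 2.07 (n = 2). An intergenic site on chromosome 3 at 5860361 to 5860530, 109065 bp from Gm8797, reached 18.9 ± 2.85 (n = 2). A promoter site on chromosome 1 at 88277521 to 88277760 reached 17.8 ± 2.00 (n = 2). It overlapped both Hjurp, a centromere histone chaperone gene, and Trpm8. An exonic site in Lars2, the mitochondrial leucyl-tRNA synthetase gene, on chromosome 9 at 123461881 to 123462160, reached 17.2 ± 3.77 (n = 2). The promoter of Gm21887 on the X chromosome at 170009841 to 170010160 had a signal of 22.5 in replicate 1 and 11.6 in replicate 2. The other sites were promoters, among them those of Rab11b (16.3 ± 0.58), Dnpep (15.2 ± 3.63) and Acin1 (14.6 ± 0.29; n = 2 each). The Acin1 site also overlapped the protein-coding gene 1700123O20Rik. No filter for repeated sequence was applied here. Whether reads from further copies raised the signal of any of these sites was not tested.

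The strongest sites called in a single library lay at or near promoters. In replicate 1 they were near Tcf3 (chromosome 10, 80434081 to 80434260, signal 5.42), Rpp38 (chromosome 2, 3332881 to 3333140, 4.16), Tmem222 (chromosome 4, 133277621 to 133277840, 3.88), Mib2 (chromosome 4, 155669421 to 155669640, 3.44) and AW146154 (chromosome 7, 41499801 to 41500040, 3.28). In replicate 2 they were near Tcf3 (chromosome 10, 80433881 to 80434080, signal 5.53), A730061H03Rik (chromosome 14, 55560341 to 55560620, 5.15), Nup98 (chromosome 7, 102210101 to 102210380, 4.93), Pip4k2b (chromosome 11, 97744801 to 97745000, 4.60) and Tmem222 (chromosome 4, 133277841 to 133278000, 4.58). The sites near Tcf3 in the 2 libraries were directly adjacent, with no base between them, as were those at Tmem222.

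Of 21938 protein-coding genes, 12982 (59.2%) had a peak within 500 bp of an annotated transcript start in both libraries. A further 266 genes had one in replicate 1 only and 707 in replicate 2 only, and 7983 genes (36.4%) had none. Promoters rich in CpG dinucleotides were open far more often. In the quintile of genes with the highest ratio of observed to expected CpG, 93.7% had a promoter peak in both libraries, against 10.3% in the lowest quintile. Genes were therefore also compared with random lists matched on this ratio.

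All 22 genes of the pan-neuronal and glutamatergic list had a promoter peak in both libraries, against 59.1% of other genes (two-sided Fisher's exact test, Benjamini-Hochberg adjusted p over 24 lists 8.84e-05). Matched on CpG, random lists reached a mean of 61.4% (permutation, adjusted p = 0.00160). Syt1, which encodes the calcium sensor of synaptic vesicle release, had the highest promoter signal of the list, 3.37 ± 0.12 (SD, n = 2; chromosome 10, 108497650 to 109010982). Camk2a, a kinase of excitatory synapses, followed at 2.76 ± 0.39 (n = 2; chromosome 18, 60925618 to 60988152). The call ended when only the 5' end of each gene record was used (77.3%, exact test, adjusted p = 0.0615). All 16 immediate early genes, which neuronal activity induces, also had a promoter peak in both libraries (exact test, adjusted p = 0.00118). Homer1 (5.11 ± 0.19; chromosome 13, 93299635 to 93405129) and Egr1 (4.96 ± 0.11; chromosome 18, 34859823 to 34864984; n = 2 each) had the highest signal among them. The 16 housekeeping genes all had peaks as well, led by Rplp0 (10.1 ± 0.39) and Vcp (9.25 ± 0.92; n = 2 each). With the 5' end of the gene record alone the housekeeping call ended (81.3%, exact test, adjusted p = 0.0557). The immediate early call stayed (87.5%, exact test, adjusted p = 0.0185). Against CpG-matched lists, neither the immediate early list (permutation, adjusted p = 0.0898) nor the housekeeping list (permutation, adjusted p = 0.0501) passed the threshold.

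Lists of genes that mark individual hippocampal fields had promoter peaks at shares from 58.3% to 80%. Promoter peaks in both libraries were found at 8 of 10 dentate granule cell genes, 6 of 8 CA1 genes and 7 of 12 CA3 and CA2 genes, and none of these 3 lists passed the exact test (adjusted p = 0.323, 0.613 and 1). C1ql2 (1.07 ± 0.01; chromosome 1, 120340582 to 120343174) and Prox1, the transcription factor of granule cells (1.02 ± 0.11; chromosome 1, 190118035 to 190170714), led the dentate list. Dsp and Lct had no promoter peak in either library. Wfs1 (4.40 ± 0.64; chromosome 5, 36966104 to 36989205) and Pou3f1 (2.21 ± 0.40; chromosome 4, 124656807 to 124660655) led the CA1 list, and Fibcd1 had no promoter peak. Pcp4 (2.61 ± 0.47; chromosome 16, 96467606 to 96525793) and Nectin3 (2.12 ± 0.57; chromosome 16, 46387706 to 46498525) led the CA3 and CA2 list, while Cacng5 and Coch had none (n = 2 for each value). The side of other genes on which these lists lay depended on the setting. With the stricter peaks the dentate and CA1 shares were 50% each, below the 53.3% of other genes, and with the 5' end of the gene record alone the CA1 share was 37.5%. Without replicate 1 the CA3 and CA2 share was 66.7%, above the 62.4% of other genes.

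The interneuron list did not pass the main test, and its call depended on the setting. Of 18 GABAergic interneuron genes, 7 had a promoter peak in both libraries (38.9%, exact test, adjusted p = 0.162). Adarb2 (1.42 ± 0.05) and Cnr1, the cannabinoid receptor gene (1.26 ± 0.21; n = 2 each), had the highest signal, and Dlx2 and Reln had no promoter peak. The list passed the threshold in the lower direction against CpG-matched lists, whose mean was 71.6% (permutation, adjusted p = 0.00576), and with the stricter peaks (16.7%, exact test, adjusted p = 0.00480). In either library alone 10 of the 18 genes (55.6%) had a promoter peak, and the list did not pass the exact test (adjusted p = 0.838 without replicate 1 and 0.926 without replicate 2).

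The lists of glial and vascular genes were each compared with all other genes, and not with one another. Promoter peaks in both libraries were found at 10 of 12 astrocyte genes, 10 of 13 oligodendrocyte genes and 5 of 8 oligodendrocyte precursor genes, shares that did not pass the exact test (adjusted p = 0.223, 0.371 and 1). Glul, the glutamine synthetase gene (3.83 ± 0.16; chromosome 1, 153899944 to 153909723), and Aldoc (2.45 ± 0.49) led the astrocyte list, and Aqp4 had no promoter peak. Mbp, the myelin basic protein gene (2.31 ± 0.40; chromosome 18, 82475146 to 82585637), and Olig1 (1.80 ± 0.01) led the oligodendrocyte list. Vcan (1.18 ± 0.19) and Cspg5 (1.16 ± 0.06; n = 2 for each value) led the precursor list, in which Cspg4 and Neu4 had none. Microglial genes were below other genes, with 2 of 14 (14.3%, exact test, adjusted p = 0.00373). Among them was the chemokine receptor gene Cx3cr1 (0.368 ± 0.037, n = 2), and C1qa and C1qb had no promoter peak. The microglial call ended against CpG-matched lists (mean 32.6%, permutation, adjusted p = 0.253). It also ended with a 2000 bp window (35.7%, exact test, adjusted p = 0.0818) and without replicate 1 (35.7%, exact test, adjusted p = 0.0959), and without replicate 2 the share was 28.6% (exact test, adjusted p = 0.0498). Of 13 endothelial and mural genes only Kdr had a peak in both libraries (0.357 ± 0.034, n = 2; exact test, adjusted p = 8.30e-04). Abcc9 and Cdh5 were among those with none. In a single library the share was larger and the list still lower, with 3 of 13 (23.1%, exact test, adjusted p = 0.0160) without replicate 1 and 2 of 13 (15.4%, adjusted p = 0.00357) without replicate 2.

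Lists for neighbouring brain regions held promoters with and without peaks. Of 10 choroid plexus and ependyma genes only Foxj1, a transcription factor of ciliated cells, had a peak in both libraries (3.98 ± 0.29, n = 2; exact test, adjusted p = 0.00477). The call ended without replicate 2, where 3 of 10 were open (30%, exact test, adjusted p = 0.100). Ccdc153 and Clic6 had none. The thalamus (5 of 8), striatum (5 of 10), neocortical layer (7 of 10) and cerebellum (4 of 10) lists did not pass the exact test (adjusted p = 1, 0.650, 0.857 and 0.446). Tle4 had the highest signal of the neocortical list, 13.7 ± 1.46 (chromosome 19, 14448150 to 14598051), followed by Etv1 at 1.81 ± 0.20. Rora (1.37 ± 0.29) and Tcf7l2 (0.958 ± 0.018) led the thalamus list, Ppp1r1b (1.43 ± 0.08) the striatum list, and Cbln1 (1.59 ± 0.08) and Calb1 (0.813 ± 0.053) the cerebellum list (n = 2 for each value). Calb1 is also in the dentate list. No promoter peak was found at Gbx2 or Lef1, Drd2 or Isl1, Lamp5 or Rspo1, and Barhl1 or Eomes. The thalamus share fell from 62.5% to 37.5% with the stricter peaks, below other genes, and without replicate 1 the striatum share rose from 50% to 70%, above them. With a 2000 bp window all 10 neocortical genes had a peak (exact test, adjusted p = 0.0374).

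Most genes used in other tissues had no promoter peak. Promoter peaks in both libraries were found at 1 of 14 liver genes, 1 of 12 skeletal muscle genes, and 2 of 10 genes each in the erythroid, T cell and germline lists. All 5 lists were lower than other genes by the exact test (adjusted p = 4.54e-04, 0.00118, 0.0358, 0.0358 and 0.0358). Of 39 Hox genes, which pattern the body axis, 2 were open, Hoxa7 (1.25 ± 0.14) and Hoxc5 (0.408 ± 0.165; n = 2 each; exact test, adjusted p = 1.25e-11). Of 1135 olfactory receptor genes, 20 were open (1.76%, with an exact p below the smallest number the software holds), led by Olfr317 (0.914 ± 0.102) and Olfr1392 (0.797 ± 0.065; n = 2 each), and Olfr1 and Olfr10 had none. Without replicate 1 the olfactory receptor share was 3.79%, and without replicate 2 it was 2.20%. Albumin (Alb), Ahsg, Acta1, Actn3, Alas2, Epb42, Cd2, Cd3d, Ddx4, Figla and Hoxa11 had no promoter peak in either library. Exceptions with high signal were Gdf9, an oocyte growth factor gene (9.21 ± 1.94; chromosome 11, 53431023 to 53437904), and Mylpf, a muscle myosin light chain gene (6.57 ± 0.58; chromosome 7, 127208890 to 127214298). Epor (1.45 ± 0.11), Lck (1.24 ± 0.12), Dazl (1.01 ± 0.02), Foxp3 (0.667 ± 0.181) and Apoh (0.627 ± 0.013) were also among the open members (n = 2 for each value). A peak counted for every gene whose promoter window it touched, at any annotated start. Such a signal can therefore belong to a neighbouring gene, which was not checked. The positions given are those of the genes and not of the peaks. Against CpG-matched lists the liver, erythroid and T cell calls ended (permutation, adjusted p = 0.0995, 1 and 0.587). The liver share was 7.14% against a matched mean of 31.7%, the T cell share 20% against 35.5% and the erythroid share 20% against 23.4%. In that comparison skeletal muscle, germline, Hox and olfactory receptor genes were called lower. Under other windows and with the stricter peaks the skeletal muscle, erythroid, T cell and germline calls each ended at least once, with exact adjusted p between 0.0742 and 0.0911.

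**Figure D2:**
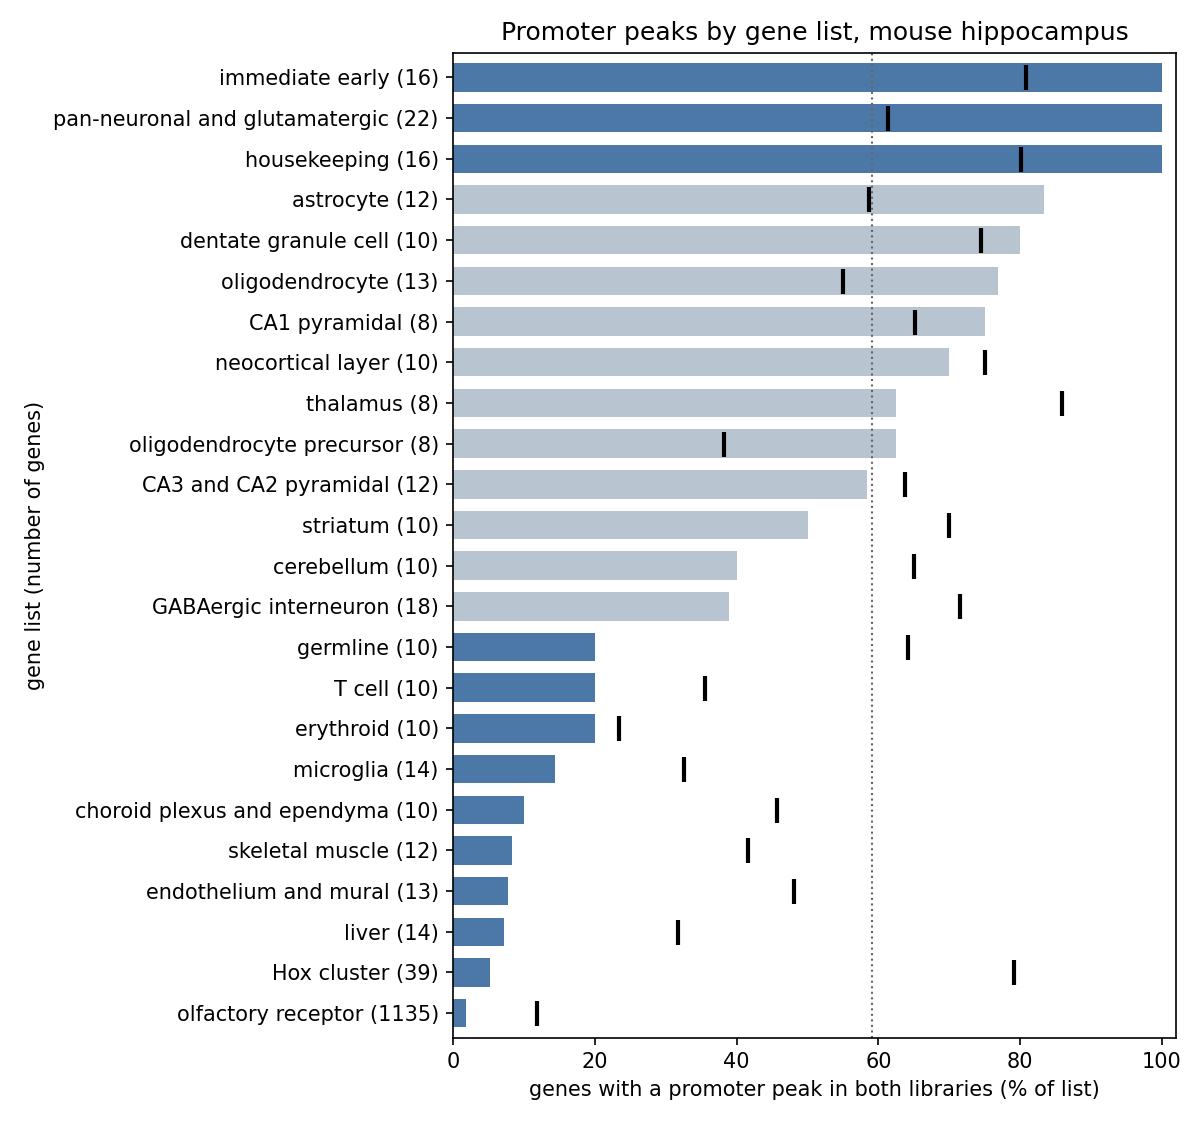
Bars show the percentage of each gene list (vertical axis, number of genes in brackets) with a promoter peak in both libraries, dark where the list differed from all other protein-coding genes by Fisher's exact test and light where it did not. Black ticks mark the mean of 10000 CpG-matched random lists and the dotted line the 59.2% of all protein-coding genes; pan-neuronal, immediate early and housekeeping genes reached 100% and olfactory receptor genes 1.76%.

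The files listed 244447 footprints in replicate 1 and 251726 in replicate 2, with a median width of 9 bp, and 89.4% and 91.5% of them overlapped a peak. They covered 13.1% and 10.3% of peak bases. Of the replicate 1 footprints, 45.3% overlapped a replicate 2 footprint by at least 1 bp (Wilson 95% interval 45.1 to 45.5%), and 44.3% the other way (44.1 to 44.5%). For footprints inside peaks the shares were 46.8% and 44.9%, against 27.4% and 26.1% when each footprint was moved at random within its own peak. Genes with a promoter peak in both libraries had a median of 5 footprints in their promoter peaks in each library. Immediate early genes had medians of 8.5 in replicate 1 and 7 in replicate 2, housekeeping genes 7 and 5, and the pan-neuronal list 5.5 in both. Dentate granule cell and GABAergic interneuron genes had medians of 2 in both libraries. With a 2000 bp window the interneuron median over both libraries was 6.5 and the dentate median 3, against 6 for all genes, so the low interneuron number held for the narrower window alone. In that wider window the immediate early median was 12.5, the pan-neuronal median 9.25 and the housekeeping median 7. These medians carry no test, and stronger peaks can show more footprints.

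Matches to the motifs of CTCF, the proneural NEUROD family, CREB, EGR and ETS factors lay in footprints more often than both comparison sequences used. A match counted when at least 0.5 of its bases were in footprints. Placement kept the length and the peak, but not base composition or position within the peak. Whether a factor was bound at these matches was not tested. Whether the enzyme by itself cuts these sequences less often was not tested either. CTCF, an insulator protein, had 82.6% ± 0.21 of its matches in footprints (n = 2; 3985 matches in replicate 1 and 5238 in replicate 2). The same length placed anywhere in the same peaks gave 20.7% ± 0.48. Outside promoters the CTCF share was 82.3% ± 0.04 (n = 2) against 0% for the reversed motif, whose 3 and 2 matches were too few to keep the call in replicate 2 (exact adjusted p = 0.0147 and 0.0729). The cAMP response element bound by CREB reached 71.8% ± 5.48, against 14.6% ± 0.83 for the reversed motif and 24.4% ± 2.32 by placement. EGR sites reached 62.2% ± 4.77, against 24.5% ± 0.58 reversed and 18.3% ± 1.80 by placement. NEUROD E-boxes reached 36.7% ± 3.68, against 7.02% ± 1.66 reversed and 10.9% ± 1.94 by placement, with 6315 and 9409 matches. ETS sites reached 30.8% ± 4.97, against 9.73% ± 0.14 reversed and 25.2% ± 2.44 by placement (n = 2 for each value).

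Against the reversed motif, 8 of 21 motifs were higher in both libraries by two-sided Fisher's exact test with Benjamini-Hochberg adjustment, and none was lower. Besides the 5 named these were AP-1, NFY and homeobox sites, and the homeobox call ended when all bases of a match had to lie in footprints (1.97% against 0%, exact adjusted p = 0.401 and 1). The reversed CTCF motif had 5 matches in replicate 1 and 4 in replicate 2, and the reversed SP/KLF motif is the same sequence, so the test was void for SP/KLF. Placement within the same peaks was therefore added after the data were seen, and it called 10 motifs higher and 1 lower. AP-1 (11.05% ± 0.02 against 9.70% ± 2.08), NFY (19.9% ± 0.45 against 20.6% ± 2.91) and homeobox sites (8.69% ± 0.83 against 10.4% ± 2.45) were not called by placement (n = 2 for each value). The libraries disagreed for AP-1, at 11.03% against 11.2% in replicate 1 and 11.06% against 8.23% in replicate 2 (permutation, adjusted p = 0.915 and 3.82e-04). NRF1 (89.4% ± 2.08 against 29.3% ± 2.08), RFX (58.6% ± 6.70 against 15.5% ± 2.40), SP/KLF (55.2% ± 4.55 against 21.6% ± 2.17), NFI (52.5% ± 14.2 against 11.3% ± 4.15) and YY1 (37.9% ± 6.04 against 25.3% ± 1.08) were called higher only by placement. The reversed motifs of NRF1, RFX, NFI and YY1 had between 2 and 9 matches per library, so the test against them could show little. GATA sites were lower by placement, 5.15% ± 0.39 against 11.7% ± 1.81, but against the reversed motif, at 3.19% ± 0.06, they lay higher without a call (n = 2 for each value; exact adjusted p = 0.149 and 0.146), so their direction depended on the comparison. REST, MEF2, SOX, PU.1, HNF1, HNF4 and TBR1 sites were called by neither comparison in both libraries. In replicate 1 alone, SOX (12.3% against 5.12% reversed), HNF4 (13.5% against 2.97%), MEF2 (13.8% against 5.83%) and NFI (62.5% against 0%) passed the exact test (adjusted p = 8.09e-04, 0.0102, 0.0311 and 0.0421). In replicate 2 they did not, and SOX ran the other way (6.36% against 7.03%). By placement, SOX was lower in replicate 2 alone (6.36% against 10.4%, permutation, adjusted p = 3.82e-04) and NFY in replicate 1 alone (20.2% against 22.7%, permutation, adjusted p = 3.50e-04).

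**Figure D3:**
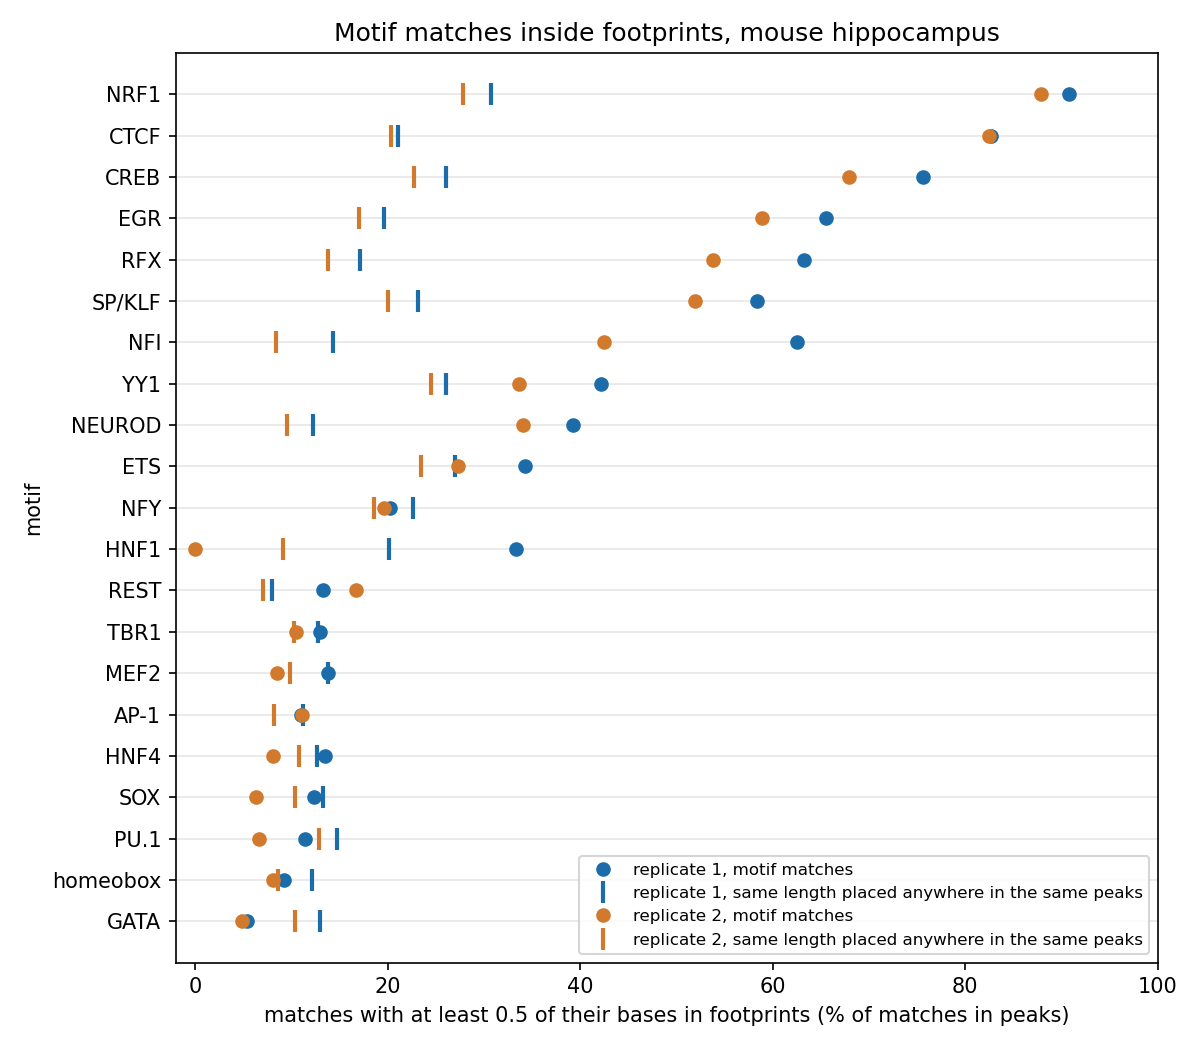
Points show the percentage of motif matches in peaks with at least 0.5 of their bases in footprints (horizontal axis) for each motif (vertical axis) and library, and short lines the percentage when the same length is placed anywhere in the same peaks. NRF1 and CTCF lie at 89.4% and 82.6% on average, and GATA sites, at 5.15%, lie below their placed value in both libraries.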

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

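The tests on Y chromosome genes in this part were chosen after the results were seen. Peaks on the Y chromosome were present in both libraries of female mice, 42 in replicate 1 and 19 in replicate 2. These peaks are counted among those above, but no comparison above looked at the Y chromosome by itself. Before position 90 Mb their median signal was 0.145 in replicate 1 and 0.159 in replicate 2, and the highest reached 0.557 and 1.02, against autosomal medians of 0.606 and 0.588. From 90 Mb onward, near the end of the chromosome, there were 20 and 5 of them, with median signals of 0.609 and 0.692 and highest signals of 6.45 and 2.62. Male tissue in the pools is argued against by 0 of 4 broadly expressed Y genes (Ddx3y, Eif2s3y, Kdm5d and Uty) having a promoter peak in either library. Their X counterparts Ddx3x, Eif2s3x, Kdm5c and Kdm6a had promoter signals of 3.88 ± 0.20, 2.86 ± 1.02, 6.37 ± 0.19 and 13.2 ± 2.64 (n = 2 each), and a male share too small to give a peak is not excluded. Placement of reads from copies elsewhere stays a candidate explanation. Of 36 bp sequences in the Y peaks, 64.5% had a further exact copy in the assembled chromosomes, against 5.68% for 500 X chromosome peaks. Copies on the Y chromosome itself were counted too. The share pools the peaks before and after 90 Mb, so it does not speak for either part alone. Where the further copies lie was not separated. Whether the peaks from 90 Mb onward lie in sequence that the Y chromosome shares with the X chromosome was therefore not tested. The design has no male library to compare with.

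Bases with a false discovery rate below 0.05 in both libraries but outside every peak amounted to 6.19 Mb, 24.9% of the 24.9 Mb listed in both. They were noted because the peak comparisons do not use them, and 0.0195 Mb of them lay more than 500 bp from a peak.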

How the results depend on the processing

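Main counts kept their side of the 1.5-fold bound except 1. Genes with a promoter peak ranged from 11683 to 13940 over the alternatives, and from 13248 to 13689 with either library alone. Called lists numbered 13 of 24 in the main test, 10 to 12 under other windows, the stricter peaks or either library alone, and 8 against CpG-matched lists, where the comparison itself holds promoter CpG fixed. Called motifs numbered 8 of 21, 7 with all bases covered or outside promoters, 11 by placement, and 8 to 12 with either library alone. Of the motifs, 5 were called against both the reversed motif and placement. Against placement, which uses another background, the difference from the comparison sequence changed sign for GATA (-6.53 percentage points, called), PU.1 (-4.78), SOX (-2.51), homeobox sites (-1.70), HNF4 (-0.943), NFY (-0.727) and MEF2 (-0.703). Of these only NFY and homeobox sites had been called higher against the reversed motif. The sign also changed for MEF2 (-0.00364) and HNF1 (-5) with all bases covered and for PU.1 outside promoters (-2.12), none of them called. With either library alone SOX ranged from -0.663 to 7.20 points and HNF1 from -20 to 33.3. The homeobox call ended with all bases covered, and the CTCF call outside promoters (82.3% against 0%, adjusted p = 0.0729, exact test), where the reversed motif had 3 and 2 matches. No value could be given there for NRF1, whose reversed motif had no match in replicate 2.

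The mean share of peaks found in the other library was 71.8% over the 2 directions of the comparison (81.6% and 62.0%, SD 13.8). Both directions count the same shared sites, so this SD reflects the unequal numbers of peaks and not a spread between replicates. The mean share was 56.8% with a reciprocal overlap of 0.5, 73.1% with the stricter peaks, 82.3% among the 50000 highest peaks and 75.3% when peaks within 200 bp counted. Spearman's rho was 0.898, moving to 0.858 among the 50000 highest peaks, whose range of signal is narrower, and to 0.908 with the stricter peaks. The mean share of footprints found in the other library was 44.8% over the 2 directions (SD 0.67, likewise not a spread between replicates). It was 31.7% with a reciprocal overlap of 0.5 and 55.0% inside peaks of both libraries. Promoter, exon, intron and intergenic shares were 28.4%, 4.44%, 33.8% and 33.3% with a 2000 bp window, which enlarges the promoter class by construction. With the stricter peaks they were 25.1%, 5.86%, 35.7% and 33.4%, and the cause was not tested. The median number of footprints per gene was 6 with a 2000 bp window, which takes in more peaks, against 5. By list, 14 of 24 such medians moved by more than the spread between libraries. For single lists, 114 alternative values kept their side of other genes and the call or its absence, 16 lost the call and 3 gained it. A further 11 changed side with no call before or after. These were the dentate, CA1 and oligodendrocyte precursor lists (50% each) and thalamus (37.5%) with the stricter peaks, CA1 and precursors (37.5% each) with the 5' end alone, and thalamus with a 2000 bp window (62.5%). Against CpG-matched lists they were thalamus (62.5%) and the neocortical list (70%). With either library alone the CA3 and CA2 share ranged from 58.3% to 66.7% and the striatum share from 60% to 70%, both changing side without replicate 1. Dividing signal by the library median kept 9 of the 10 highest sites. A promoter without a peak was not called at the authors' threshold, which does not show that it was closed.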

Other observations

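The tests on distal peaks, gene list ratios, GC content and peak placement in this part were stated before their results were seen, and the depth comparison, the trend with GC content outside promoters, the motif density, the reweighting with promoters alone and the counts of promoters open in 1 library by list were chosen after. Shared distal peaks were more numerous near genes of 4 of 11 hippocampal lists than near random lists. Of the 80698 replicate 1 peaks shared with replicate 2, 62016 did not touch a promoter window. Within genes and 20 kb on either side, immediate early genes had a median of 5.5 such peaks, against 1 for length-matched random lists, led by Fosb with 12 and Npas4 with 8. The pan-neuronal list had a median of 5, against 3, led by Syt1 with 22 and Gria1 with 21. CA1 genes had 5, against 2, with 8 at Fibcd1, which had no promoter peak. Microglial genes had 3, against 1, with 9 over the gene record of Cx3cr1 (chromosome 9, 119901616 to 120069879) and its flanks. Peaks within a gene record or its flanks can belong to neighbouring genes, which was not checked. Of 11 hippocampal lists these 4 lay above the central 95% of random lists, as did 0 of 6 lists for other tissues and 0 of 5 for neighbouring regions. The astrocyte and oligodendrocyte medians, 3 each, equalled the upper bound and were not counted, a treatment of ties settled after the results were seen. The bound stated in advance for open distal sites near genes used in the tissue was at least 5 lists, so 4 leave that hypothesis undecided. This turns on the ties, since the oligodendrocyte list lay at percentile 97.87 when ties were split, and counting it would have met the bound. Dentate granule cell (2.5 against 2.5) and endothelial and mural genes (2 against 2) did not differ from random lists.

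Distal peaks were rich in some motifs compared with sequence 2 kb away. Base composition was not matched between the peaks and that sequence, and its share in these ratios was not tested. Matches were 114 ± 15.4 times as frequent for CTCF (n = 2), 12.5 ± 1.46 times for RFX, 6.95 ± 0.65 times for NEUROD, 6.75 ± 0.05 times for EGR and 2.56 ± 0.03 times for AP-1. AP-1 matches were thus frequent in peaks, with 5850 and 8678 in distal peaks, while their placement in footprints differed between the libraries. The ratios of NRF1 (19.1 ± 9.80), NFI (10.0 ± 1.77), YY1 (7 ± 3.30) and REST (5.17 ± 2.12) rest on 3 to 8 matches 2 kb away per library. A further 7 motifs ranged from 1.10 to 3.11 times. GATA (0.529 ± 0.056), HNF4 (0.805 ± 0.043), TBR1 (0.812 ± 0.022) and SOX (0.875 ± 0.078) matches were less frequent in peaks than 2 kb away (n = 2 for each value). HNF1 had too few matches for a ratio, 3 against 7 in replicate 1 and 5 against 13 in replicate 2.

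Replicate 2 had 1.32 times as many peaks as replicate 1. Deeper sequencing is argued against, since its implied cut total was 0.762 times that of replicate 1, if both signals are scaled to the same total. Different placement of peak boundaries accounts for few of them, as 9.32% of the replicate 2 peaks without an overlap lay within 200 bp of a replicate 1 peak. Whether the rest were open in replicate 1 but short of the threshold cannot be told apart from absence. Of these peaks, 11.6% held bases below the false discovery bound in replicate 1, against 1.80% after shuffling, but that bound is also the peaks' own, so a site short of it has no listed base.

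Peaks found in replicate 1 alone lay at promoters more often than those found in replicate 2 alone, by 8.63 percentage points. More weak peaks in replicate 2 were predicted to shrink this gap among the highest peaks. It was 11.1 points for peaks among the 50000 highest of a library without an overlap among the 50000 highest of the other. Such peaks can be called at a lower rank in the other library, so this is another measure than the 8.63 points. It cannot decide whether more weak peaks in replicate 2 gave that gap. A shift in cell makeup of the pools stays open. Of 20 gene lists with at least 2 promoters open in both libraries, 1 (astrocyte genes, median log2 ratio -0.04 against 0.19) lay outside the central 95% of signal-matched random lists. That test leaves out the promoters open in a single library, 4 of the 24 lists could not enter it, and 14 of the 20 held under 10 genes. Among the lists left out, choroid plexus and ependyma had 2 promoters open in replicate 1 only and 0 in replicate 2 only, and endothelial and mural genes 1 and 2. GC content may account for most of the gap, which was 1.72 points after reweighting the replicate 2 peaks to the GC content of the replicate 1 peaks. Promoters are rich in GC, so the reweighting shrinks any such gap, but it would have left 6.78 points if promoters alone had differed. Outside promoters, the log2 ratio of replicate 2 to replicate 1 signal at shared peaks was 0.49 in the quintile with the lowest GC content and 0.10 in the quintile with the highest (Spearman rho -0.311 across peaks, which are not independent).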
